A study of Mus musculus with 16 samples.

How the data were processed

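RNA was measured by poly-A enriched paired-end sequencing of suprarenal aortae from male mice, with 4 libraries in each of 4 groups, and the labels call the 4 libraries of a group biological replicates. The groups crossed genotype (wild type, WT, or Vamp8 knockout, KO) with infusion (saline, or angiotensin II, AngII, at 1000 ng/kg/min for 5 days). Group and replicate number came from the sample titles. Per the labels' protocols, the vessels were perfused, surrounding tissue was dissected away, and aortae with bleeding in the wall or other overt pathology were left out by the submitters.

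The deposited values were raw read counts per gene, whole numbers with no normalization, in 1 column per library. Per the submitters' processing notes, the tools were HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, and the genome build was GRCm39 (mm39). The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads shared between a gene and its near-identical copies, or between overlapping genes, can therefore not be assigned with certainty. The reference used here was the GRCm38 assembly, so no coordinates are printed. It served for gene names, biotype, transcript length, GC content and which genes neighbour each other, and it held 28378 of the 29695 gene identifiers.

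The structure of the count table differed by genotype. A symbol was missing for 2725 genes, and these were exactly the 2725 genes with 0 reads in all 8 WT libraries. A further 1401 genes had 0 reads in all 8 KO libraries, and each of those had a symbol. A name table gave a symbol to 2502 of the 2725. Whether WT and KO reads were aligned and counted together is not given in the sources used here, so a difference between genotypes in the counting cannot be told apart from genotype. This limit applies to every KO against WT difference and to the interaction. The assignment of reads to copies also differed between KO saline and KO AngII, so AngII against saline within KO is not free of it either.

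Genes were kept by edgeR's default expression filter, which left 15984 genes and removed 13711. The lowest share of reads kept in a library was 99.47%. Counts were scaled by the trimmed mean of M values (TMM). The main test was edgeR's quasi-likelihood F test (R 4.3.3, edgeR 4.0.16) in a single fit of all 16 libraries with a mean per group and 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The comparisons were AngII against saline within each genotype, KO against WT within each infusion, the genotype by AngII interaction, and the average AngII effect over both genotypes. Levels are TMM-normalised CPM, read counts scaled to a common library total, given as mean ± SD over n = 4 libraries. The SE of a log2 fold change is its absolute value divided by the square root of F. The biological coefficient of variation was 35.3%. All tests were two-sided.

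Gene lists of pathways and cell type markers were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 51 lists. Lists with fewer than 5 measured genes were not tested. Each call is given beside the adjusted p with an estimated correlation, and fry was also run. A list score of a library is the mean log2 CPM of the members. Single values were compared by exact two-sided permutation tests, for which 4 libraries against 4 allow a smallest p of 0.0286. An AngII score was the mean log2 CPM of genes called higher minus that of genes called lower in the average AngII effect, and its interaction was tested over all 4900 arrangements of genotype labels within infusion. Genes near Vamp8 were compared with all others by Fisher's exact test in a window of 20 Mb.

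Named genes followed a rule. It took Vamp8, then up to 8 called protein-coding genes with the largest rise and up to 8 with the largest fall, with a CPM of at least 1 in the higher group and no overlap of the groups. It then took up to 4 called members of each list in order of camera p, or 2 members as values where none was called, to about 30 genes. Where 10 or fewer genes were called, all were named. Agtr1a, Nnt, Ddx3y and Xist were also read. Further list members and the genes of copy families, such as Timp1, Tnfrsf11b, Eln, Rnps1, Gas5 and the clock genes, were chosen after their values were seen. Groups, lists, the main tests, the naming rule and the settings to compare were fixed before the data were examined.

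The settings compared were another scaling (RLE), no filter, a stricter filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom with library quality weights, a robust fit, the replicate number as a block, the mean of the adipocyte marker lists as a covariate, only the groups compared, a fold threshold, other windows around Vamp8, and each library left out in turn. A fit without the library labelled KO saline replicate 1 and KO AngII replicate 4 was added after the data were seen. In the search for libraries far from their group, groups with 3 or fewer reads in total were left out, a choice also made after the values were seen.

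The steps were tested on simulated data with 200 changed genes and a 2-fold rise of the cell cycle list, which was left out of the false calls. Genes were drawn independently, without shared tissue or library structure. The false calls therefore do not give the error rate in the real libraries. For WT AngII against saline, over 15727 genes, 36% of 2-fold, 72% of 4-fold, 94% of 8-fold and 92% of 16-fold changes were recovered, with 10 false calls. For KO AngII against saline, over 15739 genes, the shares were 40%, 78%, 92% and 98%, with 8 false calls. For KO against WT under saline, over 15769 genes, they were 34%, 74%, 92% and 100%, with 4 false calls. No pair of libraries held the same counts. The closest pair had a Spearman correlation of 0.988 and a chi-square of 22.3 per gene, far above sampling noise. Limits from a count of 0 used 3 reads over the group and cover counting error only.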

Results

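The suprarenal aorta, the abdominal segment above the renal arteries, was sequenced in male mice lacking Vamp8 (KO) and in C57BL/6 wild-type (WT) mice. Vamp8 encodes a SNARE protein of endosomes and secretory vesicles that takes part in membrane fusion. Mice were infused for 5 days with AngII, a vasoconstrictor peptide used to provoke hypertension and aortic disease in mice, or with saline. The design asks how the aorta responds to AngII and whether loss of Vamp8 alters that response. Each of the 4 groups held 4 libraries. Total counts ran from 13284804 in WT saline replicate 1 to 21643548 in the library labelled KO saline replicate 1. None of the 4 pairwise comparisons of totals passed (lowest exact permutation p = 0.143, n = 4 per group).

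Vamp8 (ENSMUSG00000050732) was read in every library first. Its level was 51.9 ± 4.64 CPM in WT saline and 55.8 ± 3.67 CPM in WT AngII (mean ± SD, n = 4). In KO AngII it was 22.9 ± 5.90 CPM, with 14.1 CPM in replicate 4 and 24.6 to 26.7 CPM in the other libraries. In KO saline it was 34.0 ± 13.2 CPM. The library labelled KO saline replicate 1 held 826 Vamp8 reads, or 53.3 CPM after scaling. That scaled level lies within the WT range and goes against its label, while the other 3 KO saline libraries held 24.9 to 31.4 CPM. Its total count was the highest of all 16 libraries and its TMM factor, 0.716, the lowest. The low factor raises its CPM, so this level depends on the scaling. As a share of the total count, without the factor, its Vamp8 reads lay below every WT library and above every other KO library. In other genes that set the genotypes apart, chosen after their values were seen, the same library lay with KO. It held 0 reads of Trim12a (193 or more in each WT library), 72 of Rpl34 (1888 or more) and 190 of Rnps1-ps (21 or fewer), and Rnps1 was at 8.20 CPM (34.0 or more). Trim12a was named by a rule of no overlap with this library counted as KO, so its place followed from the choice. These genes cannot settle the Vamp8 genotype, since a difference in counting between genotypes was not separated from them. Vamp8 was lower in KO than in WT under AngII (log2 fold change -1.29, SE 0.23, edgeR quasi-likelihood adjusted p = 0.00981). Under saline the difference did not pass (-0.61, SE 0.23, adjusted p = 0.147). Whether the remaining reads fall outside the deleted part was not analysed here. Xist was at 8 reads or fewer and Ddx3y at 1312 to 2499 reads in all 16 libraries, as for male tissue. Nnt, part of which is deleted in C57BL/6J mice, was at 11 reads or fewer throughout.

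**Figure D1:**
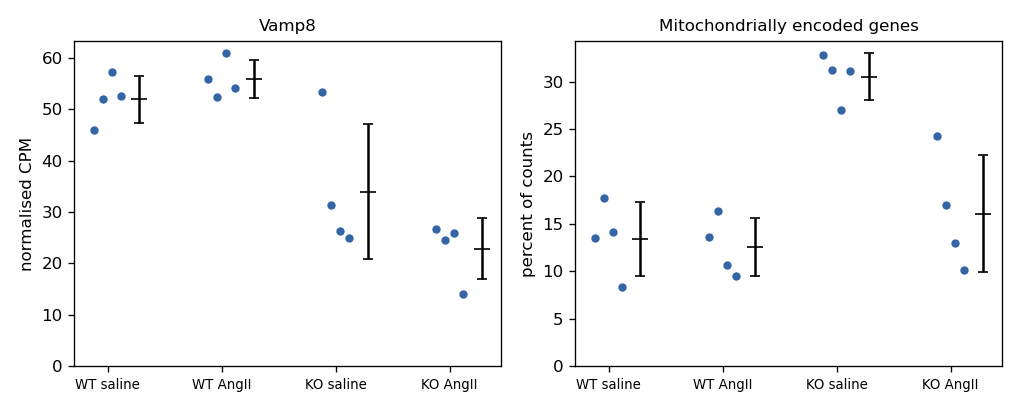
Points are libraries, and bars are the mean ± SD of 4 libraries per group. The left panel plots the normalised CPM of Vamp8, with the library labelled KO saline replicate 1 at 53.3 CPM, and the right panel plots the percent of counts from mitochondrially encoded genes, which averaged 30.5% in KO saline and 12.6% to 16.1% in the other groups.

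Libraries differed in makeup. Mitochondrially encoded genes took 13.4% ± 3.88 of counts in WT saline, 12.6% ± 3.06 in WT AngII, 30.5% ± 2.49 in KO saline and 16.1% ± 6.12 in KO AngII (SD, n = 4). KO saline lay above WT saline and above KO AngII (exact permutation p = 0.0286 for each, the smallest possible, and 0.0571 adjusted over 4 comparisons). Markers of nerve and adrenal tissue were high in KO AngII replicate 4, whose neuronal score was 8.37, against 4.11 in KO AngII replicate 2, 3.64 and 2.85 in KO saline replicates 2 and 3, and 1.84 or less in every other library. Skeletal muscle markers reached a score of 5.66 in KO saline replicate 3. Brown adipocyte markers reached 7.94 in the library labelled KO saline replicate 1, but also 7.75 in a WT saline library and 7.13 in a KO AngII library. In a principal component analysis, the first component held 29.7% of the variance and was highest in KO AngII replicate 4, and the second held 22.7% and was highest in the library labelled KO saline replicate 1.

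AngII in WT mice raised genes of cell division. Of the 28 measured genes of the cell cycle list, 16 rose and 12 did not pass, and 24 rose when adjusted over the list alone. Ccnb1, the cyclin of mitotic entry, went from 0.568 ± 0.270 to 8.89 ± 3.94 CPM (SD, n = 4), a 15.4-fold rise (log2 fold change 3.95, SE 0.59, edgeR quasi-likelihood adjusted p = 0.0105). Cdk1, its kinase partner, rose 10.7-fold, Top2a, a DNA topoisomerase of dividing cells, rose 7.92-fold, and Prc1, which bundles microtubules of the spindle, rose 8.07-fold (adjusted p = 0.00981 for each). The median log2 fold change of the list was 2.58 (camera adjusted p = 8.93e-44, adjusted p = 0.12 with an estimated correlation, fry adjusted p = 0.00706). The largest rise among named protein-coding genes was that of Spp1, the secreted matrix protein osteopontin, from 1.15 ± 0.659 to 109 ± 103 CPM (94.1-fold, log2 fold change 6.56, SE 1.27, adjusted p = 0.0342). Its level was 3.07 CPM in WT AngII replicate 2 and 63.2 to 245 CPM in the other 3 libraries of the group. The next largest rises were in Pbk, Cdc25c, Depdc1a, Hmmr, Kif2c and Cenpi, all genes of mitosis, with log2 fold changes from 4.22 down to 3.67 (adjusted p from 0.00981 to 0.0341). Vcam1, an adhesion molecule that binds leukocytes, rose 3.06-fold to 137 ± 58.1 CPM (adjusted p = 0.0415), Timp1, an inhibitor of matrix metalloproteinases, rose by 3.00 log2 units (adjusted p = 0.0415), and Tnfrsf11b, the decoy receptor osteoprotegerin, rose by 2.32 (adjusted p = 0.0207). Pced1b was the only gene called lower (log2 fold change -1.02, adjusted p = 0.0289).

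In all, 70 genes were called higher and 1 lower of 15984 tested, and 1406 had an unadjusted p under 0.05. DESeq2 called 222 higher and 58 lower, limma voom with quality weights 151 and 103, and a fit with the adipocyte score 128 and 4, so how far the response was one-sided depended on the tool. Without both KO libraries that stood apart, the count was 128. The count rested on single libraries. It was 3 without WT saline replicate 1 or replicate 4, 5 without WT saline replicate 3, and 12 without WT AngII replicate 3 or replicate 4. It was 39 without WT saline replicate 2 or KO AngII replicate 2, 109 without WT AngII replicate 2 and 115 without KO AngII replicate 4.

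Several matrix and immune lists were also higher in WT mice under AngII, although few single members passed. Camera called 14 of the 51 lists higher and 4 lower, and none was called with an estimated correlation. It called 16 higher and 2 lower without WT saline replicate 2, and 18 and 7 without WT saline replicate 4. Among matricellular proteins and proteoglycans 1 of 22 genes rose, Spp1, and 14 rose when adjusted over the list alone (median log2 fold change 1.19, camera adjusted p = 4.85e-11, adjusted p = 0.422 with an estimated correlation). The 19 collagens all had positive fold changes with a median of 0.78, and 3 rose when adjusted over the list alone (camera adjusted p = 7.62e-08, adjusted p = 0.428 with an estimated correlation). Collagen processing genes had a median of 0.49, with 3 of 20 passing over the list alone (camera adjusted p = 3.29e-09, adjusted p = 0.428 with an estimated correlation). In that list, the crosslinking enzyme Lox had 346 CPM under saline and 1005 CPM under AngII (log2 fold change 1.54, SE 0.38, adjusted p = 0.12). Elastic fibre genes had a median of 0.47 (2 higher and 1 lower of 15 over the list alone, camera adjusted p = 0.0143, adjusted p = 0.856 with an estimated correlation). Matrix metalloproteinases and related proteases had a median of 0.51 (1 of 20 over the list alone, camera adjusted p = 0.000112, adjusted p = 0.428 with an estimated correlation). Protease inhibitors had a median of 0.27, with 1 of 11 genes rising, Timp1, and 4 over the list alone (camera adjusted p = 0.00654, adjusted p = 0.428 with an estimated correlation).

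Of 23 chemokines and cytokines, 12 rose when adjusted over the list alone and none over all genes (median 0.91, camera adjusted p = 1.65e-07, adjusted p = 0.306 with an estimated correlation). Ccl12 and Ccl8, which attract monocytes, had log2 fold changes of 4.41 and 2.01 (adjusted p = 0.0774 and 0.145). Monocyte markers had a median of 1.87 (3 of 7 over the list alone, camera adjusted p = 0.00162, adjusted p = 0.422 with an estimated correlation). Macrophage markers had a median of 0.56 (0 of 18, camera adjusted p = 1.24e-05, adjusted p = 0.528 with an estimated correlation). That of lysosomal genes was 0.26 (1 of 23 over the list alone, camera adjusted p = 8.83e-07, adjusted p = 0.422 with an estimated correlation). Leukocyte adhesion molecules (median 0.47, Vcam1 called), oxidative stress genes (0.18) and antigen presentation genes (0.17) were called higher at camera adjusted p = 0.00526, 0.0184 and 0.0242. They had adjusted p = 0.466, 0.422 and 0.896 with an estimated correlation. Endothelial markers (median -0.34), mast cell markers (-0.50), lymphatic endothelial markers (-0.76) and smooth muscle contractile genes (-0.32) were called lower at camera adjusted p = 0.00264, 0.00479, 0.0148 and 0.0242. They had adjusted p = 0.810, 0.422, 0.576 and 0.938 with an estimated correlation.

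**Figure D2:**
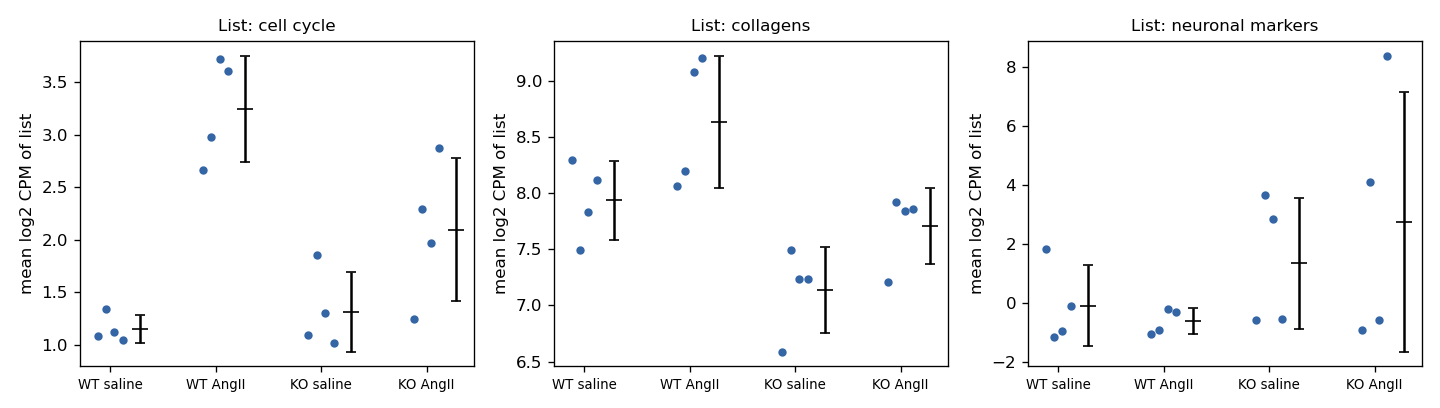
Points are libraries, and bars are the mean ± SD of 4 libraries per group. The panels plot the mean log2 CPM of the cell cycle list (mean 1.15 in WT saline and 3.25 in WT AngII), the collagens (7.94 in WT saline and 7.14 in KO saline) and the neuronal markers, where KO AngII replicate 4 sits at 8.37.

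AngII in KO mice gave 8 called genes, all lower, against a saline group that includes the library labelled KO saline replicate 1, whose scaled Vamp8 level lies in the WT range. Rps3a3 and Rps3a2, copies of the ribosomal protein gene Rps3a1, were at 156 ± 57.4 and 123 CPM in KO saline and at 2.01 ± 0.135 and 3.44 CPM in KO AngII (log2 fold changes -6.28 and -5.16, edgeR quasi-likelihood adjusted p = 5.18e-08 and 6.67e-07). Tpm3-rs7, a copy of the tropomyosin gene Tpm3, fell by 2.42 on the log2 scale (adjusted p = 0.00135). These 3 copies share sequence with their parent genes, so their reads are uncertain, and both WT groups held them near the KO AngII level, with 2.13 and 2.20 CPM for Rps3a3. Hist1h2al, a histone gene of a family of near-identical copies that the name table identified, had 407 reads over the KO saline libraries and 0 in the other 12, so it was at least 165.5-fold lower in KO AngII. Ly6c1, a surface protein of endothelial and adventitial cells, fell from 249 ± 24.7 to 119 ± 14.1 CPM (log2 fold change -1.06, SE 0.15, adjusted p = 0.0135), close to the WT levels of 114 and 111 CPM. The RNA AY036118 fell by 2.29 (adjusted p = 0.00179), the small nucleolar RNA host gene Snhg20 by 1.48 (adjusted p = 0.00430) and Prxl2c, of the peroxiredoxin-like family, by 1.00 (adjusted p = 0.0432).

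The count of genes called higher in KO AngII against KO saline was 0 by edgeR with all libraries, although 3072 genes had an unadjusted p under 0.05, and DESeq2 called 483 higher and 251 lower and limma voom 300 higher and 261 lower. The direction rested on single libraries, since edgeR called 14 higher and 18 lower without WT saline replicate 2, 16 and 14 without KO AngII replicate 1 and 8 and 9 without KO AngII replicate 4. With the adipocyte score edgeR called 4 higher and 13 lower. RLE scaling and no filter each gave 7 called genes, all lower.

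Camera called 6 lists higher and 7 lower in this comparison, and none was called with an estimated correlation (lowest adjusted p = 0.966). Without KO AngII replicate 4 it called 9 higher and 3 lower. Cell cycle genes had a median log2 fold change of 0.96, with 6 higher and 1 lower of 28 over the list alone (camera adjusted p = 1.26e-05, adjusted p = 0.966 with an estimated correlation). Top2a had 3.55 ± 2.09 CPM under saline and 12.2 ± 6.04 CPM under AngII (log2 fold change 1.79, SE 0.42, adjusted p = 0.106) and Mki67 4.73 ± 2.18 and 13.8 ± 6.28 CPM (1.55, SE 0.39, adjusted p = 0.113). Collagens had a median of 0.63 (camera adjusted p = 9.31e-05), matricellular genes 0.70 (4 of 22 over the list alone, camera adjusted p = 0.000782) and collagen processing genes 0.43 (camera adjusted p = 0.00348). TGF-beta pathway genes had a median of 0.39 (6 of 17 over the list alone, camera adjusted p = 0.00869) and heat shock proteins 0.69 (8 of 13 over the list alone, camera adjusted p = 0.00343), all 5 lists with adjusted p = 0.966 with an estimated correlation. Periostin (Postn), a matrix protein of injured tissue, had 687 CPM under saline and 2081 CPM under AngII (log2 fold change 1.60, SE 0.36, adjusted p = 0.106).

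The mitochondrial share was 30.5% in KO saline and 16.1% in KO AngII, and mitochondrial lists were among those that were lower. Mitochondrially encoded genes had a median of -1.34, with 12 of 13 passing over the list alone (camera adjusted p = 1.34e-09). Oxidative phosphorylation genes (median -0.69, none of 25 passing, camera adjusted p = 0.00112), fatty acid oxidation genes (-0.60, 0.00869) and brown adipocyte markers (-0.88, 0.00869) were also lower. So were ribosomal proteins (-0.18, 0.000563), endothelial markers (-0.47, 2 of 17 over the list alone, 0.000112) and fibroblast markers (-0.08, 0.0470), all with adjusted p = 0.966 with an estimated correlation. Fold changes in KO AngII against saline also followed transcript length across genes (Spearman 0.338 over 15797 genes, which are not independent replicates), against -0.111 in WT mice. For KO against WT the values were -0.276 under saline and 0.101 under AngII. Neuronal markers had a median of 4.36, with 9 of 10 passing over the list alone and a camera adjusted p of 0.210, and they were highest in KO AngII replicate 4.

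The response to AngII was then compared between genotypes. By edgeR's quasi-likelihood test of the interaction, 3 genes were called, the copies Rps3a3 (log2 fold change -6.32, adjusted p = 2.28e-06), Rps3a2 (-5.16, adjusted p = 2.86e-05) and Tpm3-rs7 (-2.75, adjusted p = 0.0152), each with its high level in KO saline alone. No gene called for AngII in WT mice was called in KO mice, but none of those 71 genes passed the interaction either, so a difference in their response was not shown. For Spp1 the log2 fold change was 6.56 in WT and 0.67 in KO (interaction -5.89, SE 1.61, adjusted p = 0.361). For Vcam1 the values were 1.62 and -0.16 (interaction -1.78, SE 0.45, adjusted p = 0.361) and for Timp1 3.00 and 0.49 (interaction -2.51, SE 0.81, adjusted p = 0.391). The interaction of Cdk1 was -2.74 (SE 0.62, adjusted p = 0.361). In all, 1793 genes had an unadjusted p under 0.05, and 3 other fits called more genes higher than lower: 67 higher and 37 lower by DESeq2, 123 and 50 by voom, and 8 and 4 by edgeR without WT saline replicate 2.

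Averaged over both genotypes, AngII raised 137 genes and lowered 29 (edgeR, adjusted p under the same threshold). DESeq2 called 463 higher and 203 lower and limma voom 314 and 235, and edgeR with 1 library left out called 42 to 252 in all. A score of the 166 genes that edgeR called with all libraries rose by 2.55 log2 units in WT and by 2.58 in KO mice. The difference was 0.03 (exact permutation p = 0.965 over 4900 arrangements), which does not show equal responses. The median absolute log2 fold change of the same genes was 1.79 in WT and 1.08 in KO. A score of those with an absolute log2 fold change of at least 1 gave a difference of 0.21. Copies with uncertain reads were not screened out of the score, so a fall of Rps3a3, Rps3a2 or Tpm3-rs7 in KO alone could raise its KO effect. Within a genotype the smallest p that 4 against 4 allow was reached in both (exact permutation p = 0.0286), on genes chosen from the same libraries. Over all 15984 genes, 52.2% had the same sign in both genotypes, with a Pearson correlation of 0.033 and a Spearman correlation of 0.093 across genes, which are not independent replicates. Like signs among the 166 genes follow largely from their selection on the average of both effects and say nothing of agreement. With 1 library left out, the difference in score ran from -0.45, without WT saline replicate 2, to 0.55, without WT AngII replicate 3. It was negative also without WT AngII replicate 2 (-0.25) and positive without each of the other 14 libraries.

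By camera, 3 lists were called higher and 12 lower in the interaction, with adjusted p = 0.837 with an estimated correlation for each. Cell cycle genes had a median interaction of -1.40 (10 of 28 lower over the list alone, camera adjusted p = 1.89e-09), chemokines and cytokines -0.85 (camera adjusted p = 0.000524). Macrophage markers had -0.61 (0.00734), lysosomal genes -0.34 (0.00164) and heat shock proteins 1.02 (4 of 13 higher over the list alone, 0.000922). Mitochondrially encoded genes were at -1.19 (camera adjusted p = 5.76e-07), oxidative phosphorylation genes at -0.67 (0.00109), fatty acid oxidation genes at -0.59 (0.00513) and brown adipocyte markers at -0.91 (0.00734), which moved with the mitochondrial share of KO saline. Smooth muscle contractile genes (0.65, 0.00164), cholesterol biosynthesis genes (0.67, 0.00513), ribosomal proteins (-0.14, 0.00734), fibroblast markers (-0.44, 0.0320), oxidative stress genes (-0.40, 0.0445) and osteochondrogenic genes (-0.41, 0.0467) were the other lists called. Without KO AngII replicate 4 camera called 3 lists higher and 6 lower.

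KO and WT aortae under saline differed in genes of the extracellular matrix and the mitochondrial genome, with the library labelled KO saline replicate 1 counted as KO. Its scaled Vamp8 level goes against its label. Its Trim12a, Rpl34 and Rnps1 lie with KO, but they were chosen after their values were seen and cannot settle the label. Elastin (Eln), the main elastic protein of the arterial wall, was at 5768 ± 2601 CPM in WT and 1591 ± 310 CPM in KO (log2 fold change -1.86, SE 0.39, edgeR quasi-likelihood adjusted p = 0.0232). Serpinh1, the collagen chaperone, fell from 918 to 281 CPM (3.26-fold, adjusted p = 0.00135). Of 19 collagens 8 fell and 11 did not pass (12 lower over the list alone). Col15a1, Col6a2, Col6a1 and Col4a2 had log2 fold changes of -1.25, -1.19, -1.17 and -1.04 (adjusted p = 0.0187, 0.0199, 0.0214 and 0.0287). In all, camera called 13 lists higher and 9 lower, and none was called with an estimated correlation. The median of the collagens was -1.17 (camera adjusted p = 3.01e-08, adjusted p = 0.805 with an estimated correlation). Collagen processing genes (3 of 20 lower, 12 over the list alone, median -0.63, camera adjusted p = 4.23e-07) were lower. So were elastic fibre genes (2 of 15 lower, 8 over the list alone, median -0.75, 0.000140) and unfolded protein response genes (5 of 18 lower, 10 over the list alone, median -0.51, 0.000140). All 3 lists had adjusted p = 0.805 with an estimated correlation. Matricellular genes (4 of 22 lower, 7 over the list alone, median -0.73, camera adjusted p = 0.000287) and contractile genes (none of 19 called, 7 lower over the list alone, median -0.87, 5.38e-05) followed. TGF-beta genes (1 of 17 lower, median -0.45, 0.00623) and heat shock proteins (none of 13, median -0.54, 0.0152) were also called, all 4 lists with adjusted p = 0.824 with an estimated correlation. Mast cell markers were lower as well (median -0.92, camera adjusted p = 0.0238, adjusted p = 0.805 with an estimated correlation). The general adipocyte score was 8.08 ± 0.35 in KO saline and 7.25 ± 0.95 in WT saline (SD, n = 4). Of 76 matrix genes 17 were called, and 7 of these 17 stayed called with an adipocyte score as covariate. Matrix genes called only with the covariate were not counted. The median log2 fold change of all 76 was -0.38 with the covariate, against -0.78 without it.

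Mitochondrially encoded genes were higher in KO saline. Of 13 genes 6 rose, and 13 did when adjusted over the list alone (median 1.64, camera adjusted p = 5.69e-10, adjusted p = 0.805 with an estimated correlation). The complex I subunit mt-Nd1 went from 14963 ± 4840 to 46589 ± 8509 CPM (3.11-fold, adjusted p = 0.0334) and mt-Nd3 from 184 ± 85.8 to 993 ± 619 CPM (5.40-fold, adjusted p = 0.0325). Oxidative phosphorylation genes of the nucleus (median 0.75, camera adjusted p = 8.57e-05), fatty acid oxidation genes (0.74, 0.000493), general adipocyte markers (0.73, 0.00859) and brown adipocyte markers (0.83, 0.0375) were called higher as lists, with no single member called. Called higher too were skeletal muscle markers (11 of 11 over the list alone, 3.87, 0.0364), endothelial markers (2 of 17 rose, 6 over the list alone, 0.57, 0.000146) and lymphatic endothelial markers (1.14, 0.0364). Ribosomal proteins (0.18, 0.00242), chemokines and cytokines (0.72, 0.0134) and glycolysis genes (0.61, 0.0405) were also called higher. These 10 lists each had adjusted p = 0.824 with an estimated correlation. Antigen presentation genes had a median of 0.64 (1 of 16 rose, B2m, 10 over the list alone, camera adjusted p = 5.38e-05, adjusted p = 0.805 with an estimated correlation). Brown adipocyte markers were highest in the library labelled KO saline replicate 1 and skeletal muscle markers in KO saline replicate 3.

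Among named protein-coding genes with at least 1 CPM and no overlap of the groups, the largest rise in KO saline was in Gbp2b, an interferon-induced guanylate-binding protein (0.112 to 37.8 CPM, log2 fold change 8.37, SE 0.65, edgeR quasi-likelihood adjusted p = 2.22e-06). Next were Atp1a4 (6.20, adjusted p = 0.00147), Ifi202b, an interferon-inducible gene (5.42, adjusted p = 1.21e-05), Rdh16, Pik3c2g, Adcy1, Trim34b and Ctse (from 5.31 down to 3.49). Hist1h2al, not annotated as protein-coding, had 407 reads in KO saline and 0 in WT saline, so it was at least 156-fold higher against a floor of 3 reads over the group. By the same rule, the largest falls were in Trim12a (17.9 to 0.0999 CPM, -7.33, adjusted p = 0.0212), Trim30d (-6.59, adjusted p = 0.0193) and Trim5 (-5.91, adjusted p = 0.0116). Igsf9 (-4.15, adjusted p = 0.000329) came next, then Cilp2, Tceal6, Vtcn1 and Dsp (from -2.82 to -2.53). Gbp2b, Ifi202b and the Trim genes belong to families of close paralogs, so some of their reads may be shared. Whether shared reads or a difference in the DNA of the animals accounts for these differences was not tested. KO AngII replicate 4 held 116 reads of Trim12a against 6 or fewer in the other KO libraries and 193 or more in every WT library. In all, 197 genes were called higher and 284 lower, with an unadjusted p under 0.05 for 3492, and pseudogenes were called higher 43 times and lower 6 times of 724 tested.

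The call count under saline moved with single libraries and settings, with DESeq2 at 479 higher and 883 lower, voom at 1534 and 1663, the adipocyte score at 106 and 86 and a fit of these groups alone at 96 and 107. It was 105, 127 and 120 without WT saline replicates 1, 3 and 4, and 1744 without WT saline replicate 2. It was 197, 163, 191 and 201 without KO saline replicates 1 to 4, 304 without WT AngII replicate 1 and 857 without KO AngII replicate 4. A difference in counting between genotypes cannot be told apart from genotype here.

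**Figure D3:**
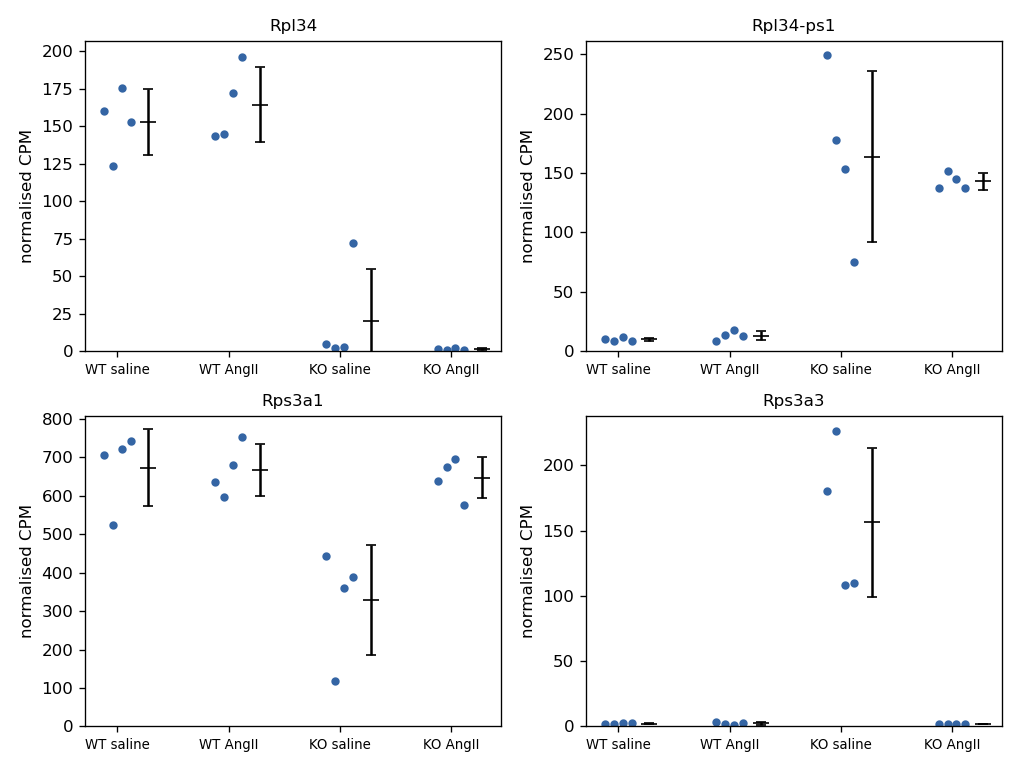
Points are libraries, and bars are the mean ± SD of 4 libraries per group, in normalised CPM. Rpl34 is low and its copy Rpl34-ps1 high in the KO groups, and Rps3a1 is lower and its copy Rps3a3 higher in KO saline alone.

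In some families the reads of a parent gene and of its processed copies differed in opposite directions between genotypes. Families were taken by a copy's name, the parent's with a suffix, and the Rps3a1 family was added after its values were seen. Of 15 parents of such a copy called higher under saline, 10 had a lower level in KO, of which Rnps1 was called, and 5 a higher one, of which Ftl1 was called (log2 fold change 0.95, edgeR quasi-likelihood adjusted p = 0.0192). Rpl34, a ribosomal protein gene, was at 153 ± 22 CPM in WT saline and 164 ± 25.0 CPM in WT AngII, and at 20.4 ± 34.5 and 1.29 ± 0.675 CPM in KO saline and KO AngII (SD, n = 4). Its copy held 6.14% and 7.46% of the reads of the pair in the WT groups and 86.5% and 99.1% in the KO groups. KO saline replicate 4 was intermediate, with 1083 reads on the parent and 1126 on the copy. The sum of the pair was 163 to 184 CPM in WT saline, WT AngII and KO saline and 144 CPM in KO AngII. Copies of Rps3a1 held 46.7% of the family in KO saline and 0.840% to 0.900% in the other groups. Rnps1, a splicing factor gene whose copy Rnps1-ps rose in KO by 4.92 and 6.31 log2 units, had log2 fold changes of -1.81 and -1.76 under saline and AngII (adjusted p = 6.98e-07 and 1.28e-06), and Gas5, a noncoding RNA that hosts small nucleolar RNAs, -4.06 and -4.62 (adjusted p = 4.12e-07 and 1.35e-07).

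Under AngII, KO aortae again held less RNA of matrix genes than WT aortae. Collagen processing genes fell in 6 of 20 cases, 17 over the list alone (median -0.82, camera adjusted p = 5.43e-14). Collagens fell in 9 of 19, 12 over the list alone (median -0.99, camera adjusted p = 3.05e-12). Both lists had adjusted p = 0.373 with an estimated correlation and a fry adjusted p of 0.0477. Lox fell from 1005 to 250 CPM (4.03-fold, SE 0.39 on the log2 scale, edgeR quasi-likelihood adjusted p = 0.0155) and Serpinh1 2.65-fold (adjusted p = 0.00642). Bmp1 fell 2.39-fold and Plod2 2.41-fold (adjusted p = 0.0322 and 0.0361) and Col5a2 3.14-fold (adjusted p = 0.0207). Eln had 17390 ± 6200 CPM in WT AngII and 3269 ± 1090 CPM in KO AngII (log2 fold change -2.41, SE 0.40, adjusted p = 0.00614). Of the 76 matrix genes, 23 were called, and all 23 stayed called with an adipocyte score as covariate. Those called only with the covariate were not counted. The median of all 76 was -0.73 with the covariate, against -0.89 without it. Elastic fibre genes fell in 4 of 15 cases and rose in 1, Efemp1 (10 lower and 1 higher over the list alone, median -0.64, camera adjusted p = 4.15e-06). Matricellular genes fell in 3 of 22 cases (10 over the list alone, median -0.91, camera adjusted p = 3.10e-09), both lists with adjusted p = 0.373 with an estimated correlation. Acan, the proteoglycan aggrecan, fell 17.2-fold (adjusted p = 0.000303), Sparc, a collagen-binding glycoprotein, 3.06-fold (adjusted p = 0.00525) and Spp1 30.7-fold (adjusted p = 0.0419).

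Camera called 9 lists higher and 13 lower in KO AngII against WT AngII, and none was called with an estimated correlation (lowest adjusted p = 0.212). Cell cycle, macrophage, lysosomal and complement lists were among those lower, while antigen presentation was called higher and chemokine, monocyte, dendritic and T cell lists were not called (camera adjusted p from 0.191 to 0.635). With an estimated correlation the adjusted p was 0.373 for cell cycle, macrophage and lysosomal lists and 0.686 for complement and antigen presentation. Cell cycle genes had a median of -1.25, with 0 of 28 called by edgeR and 20 lower over the list alone (camera adjusted p = 2.52e-16, fry adjusted p = 0.0477), and Cdk1 had a log2 fold change of -1.65 (SE 0.43, adjusted p = 0.0579). Macrophage markers had a median of -0.90 (11 of 18 lower over the list alone, camera adjusted p = 2.96e-08), lysosomal genes -0.35 (4 of 23 fell, Ctsc, Ctsk, Hexa and Gusb, 6 over the list alone, 7.10e-07) and matrix metalloproteinases -0.57 (7 of 20 lower over the list alone, 1.19e-05). Unfolded protein response genes had a median of -0.51 (3 of 18 fell, 10 over the list alone, 5.88e-06) and osteochondrogenic genes -0.78 (2 of 14 fell, 4 over the list alone, 0.00344). These 6 lists each had adjusted p = 0.373 with an estimated correlation. Ctsk, a collagen-degrading cathepsin, fell 2.70-fold (adjusted p = 0.0245). Fibroblast markers (-0.52, camera adjusted p = 0.000533, adjusted p = 0.557 with an estimated correlation), protease inhibitors (-0.44, 0.0410, 0.557 likewise) and complement genes (-0.27, 0.0378, 0.686 likewise) were also called lower.

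By the same naming rule, the largest rises in KO AngII were led by genes of neurons and neuroendocrine cells. Sult4a1, a brain sulfotransferase, Chrm2, a muscarinic receptor, Prph, the intermediate filament of peripheral neurons, Scg5, Sv2c and Mapk8ip2 had log2 fold changes from 10.73 to 7.78 (edgeR quasi-likelihood adjusted p from 0.0385 to 0.0495). They moved with the neuronal score, and KO AngII replicate 4 held 4551 reads of Sult4a1 and 11595 of Prph, against 261 or fewer and 617 or fewer in every other library. Neuronal markers were called higher (1 of 10 rose, 10 over the list alone, median 8.73, camera adjusted p = 0.0202, adjusted p = 0.751 with an estimated correlation). So were adrenal (1 of 6 rose, 6 over the list alone, 6.99, 0.00546, adjusted p = 0.413 with an estimated correlation) and Schwann cell markers (9 of 11 over the list alone, 3.04, 0.000165, adjusted p = 0.557 with an estimated correlation). Lymphatic endothelial markers were called higher (5 of 6 over the list alone, 1.62, 0.00182, adjusted p = 0.383 with an estimated correlation). Endothelial markers (0.45, 0.00285), general adipocyte markers (0.43, 0.00546) and antigen presentation genes (0.30, 0.0147) followed, each with adjusted p = 0.686 with an estimated correlation, as did cholesterol biosynthesis genes (0.64, 0.000270, adjusted p = 0.557 with an estimated correlation). Ifi202b rose by 8.22 and Gbp2b by 7.65 on the log2 scale (adjusted p = 1.65e-06 and 4.56e-06). The largest falls by this rule were in Rpl34 (-6.98), Ifi213 (-6.06), Acan, Aoah (-3.74), Igsf9 (-3.66), Cd300ld, Zfp429 and Ms4a14 (-2.65), with adjusted p from 0.000303 to 0.0425.

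Between KO and WT under AngII, 159 genes were called higher and 165 lower, with an unadjusted p under 0.05 for 2860. DESeq2 called 718 higher and 512 lower, voom 250 and 330, the adipocyte score fit 356 and 318 and a fit of these groups alone 52 and 50. The balance of directions turned with single libraries, with 475 higher and 149 lower without KO AngII replicate 1, 561 and 284 without KO AngII replicate 3, and 119 and 280 without WT AngII replicate 2. The count was 169, 100 and 103 without WT AngII replicates 1, 3 and 4, and 151 and 207 without KO AngII replicates 2 and 4. It was 206, 176 and 198 without KO saline replicates 2 to 4. A difference in counting between genotypes cannot be told apart from genotype here either.

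The genotype difference was compared between infusions, which share no library but were tested in a single fit with dispersions estimated over all libraries. Of the genes called higher in KO, 67 were shared, against 1.96 from independent lists. Of those called lower, 66 were shared, against 2.93, and no gene was called in opposite directions. Independent lists take every gene as equally easy to call, so these expectations may be too low. A difference in counting between genotypes would be shared by both infusions as well. Across all 15984 genes the fold changes had a Pearson correlation of 0.521 and a Spearman correlation of 0.349. Of the 227 tested genes within 20 Mb of Vamp8, 4 were called under saline (1.76%, against 3.04% elsewhere, odds ratio 0.571, Fisher's exact p = 0.331) and 6 under AngII (2.64%, against 2.02%, odds ratio 1.32, Fisher's exact p = 0.471). Within 10 Mb the odds ratio was 1.09 under saline (Fisher's exact p = 0.708) and 3.42 under AngII (Fisher's exact p = 0.0350). Agtr1a, which encodes a receptor for AngII, was at 49.6 CPM in KO AngII replicate 4 and 2.56 to 7.52 CPM in the other 15 libraries, and it was called in none of the comparisons.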

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

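The tests of reads shared with copies, of separately made values, of DNA around Vamp8, of brown fat, of mitochondrial transcript length and of less arterial wall were chosen after the results were seen, while the counts of other splits of the libraries and the tests of matrix transcript length were written before. In 617 groups of 4 libraries, the gap between the highest or lowest library and its nearest neighbour was divided by the group's range, and 41 values passed Dixon's 95% limit, where chance marks about 1 in 20 groups, here 30.9. By library, KO AngII replicate 4 had 8, WT saline replicate 2 and KO AngII replicate 1 had 6 each, and the library labelled KO saline replicate 1 had 5.

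Among marker scores, lymphatic endothelial markers were low in WT AngII replicate 4 (gap over range 0.892) and in the library labelled KO saline replicate 1 (0.902), natural killer cell markers were high in WT saline replicate 2 (0.947), erythroid markers high in KO AngII replicate 3 (0.862) and general adipocyte markers low in KO saline replicate 4 (0.884). In KO AngII replicate 4, Vamp8 (0.872) and B2m (0.872) were low and Kif2c (0.934), Ccl8 (0.988), Ccr2 (0.883), Trim12a (0.889), Trim30d (0.884) and Trim5 (0.955) were high. In KO AngII replicate 1, Pced1b (0.872), Col5a2 (0.838) and Ctsk (0.921) were low and Ndufb10 (0.855), Cox5a (0.910) and Ctsz (0.978) high. In KO AngII replicate 3, Cdc25c (0.837) was low and Bmp1 (0.918) high. In the library labelled KO saline replicate 1, Ndufb10 (0.928), Sdhc (0.916), Cox5b (0.910) and Cox5a (0.860) were high. In KO saline replicate 3 Ctsl (0.845) was low, and in KO saline replicate 4 Trim12a (1.00) was high and Cilp2 (0.840) and B2m (0.901) low. In WT saline replicate 2, Postn (0.872), Tceal6 (0.949), P3h1 (0.837) and Sv2c (0.848) were low and Hmox1 (0.904) high, and in WT saline replicate 3 Depdc1a (0.862) was high and Trim34b (0.867) low. In WT AngII, Cenpi was low in replicate 1 (0.906), Adcy1 (0.844) and Actg2 (0.845) high in replicate 3, and Cx3cl1 (0.865) and Bag3 (0.834) high in replicate 4.

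The effect of AngII differed between genotypes by the interaction test for Rps3a3 (-6.32), Rps3a2 (-5.16) and Tpm3-rs7 (-2.75), all copies of other genes. By camera it differed for 15 lists, with median interactions of 0.65 for contractile genes, 0.67 for cholesterol biosynthesis, 1.02 for heat shock proteins, -0.34 for lysosomal genes, -0.85 for chemokines and cytokines, -1.40 for the cell cycle, -0.40 for oxidative stress, -0.67 for oxidative phosphorylation, -0.59 for fatty acid oxidation, -0.41 for osteochondrogenic genes, -0.14 for ribosomal proteins, -1.19 for mitochondrially encoded genes, -0.44 for fibroblast markers, -0.61 for macrophage markers and -0.91 for brown adipocyte markers. None of these lists passed with an estimated correlation (adjusted p = 0.837).

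Other splits of the same libraries were counted. For KO against WT under AngII, 1 of 35 splits, the real one with 324 genes, gave as many, and the highest other gave 3. For the average AngII effect, 1 of 100 splits, the real one with 166 genes, gave as many, and the highest other gave 5. Both shares were under the limit set beforehand, which argues against chance. They are the smallest that so few splits allow, so chance was not excluded. For the interaction 2 of 100 splits gave at least the real 3 genes, under the limit set beforehand, but another split also gave 3. These splits shuffled genotype within infusion and so removed the genotype differences as well. They cannot exclude chance for the interaction alone. For AngII in WT mice 2 of 35 splits gave at least the real 71 genes and the highest other gave 375, for AngII in KO mice 2 of 35 gave at least 8 and the highest other 114, and for KO against WT under saline 2 of 35 gave at least 481 and the highest other 1372. The shares of these 3 were not under the limit, so the splits do not argue against chance there. A split that calls several times the real number points to a structure of the samples other than the groups.

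In KO libraries, copies of some ribosomal and other genes were higher, and 10 of 15 parents of a copy called under saline were lower, 1 of them called, while 5 were higher, in families taken by name and that of Rps3a1. Reads assigned to a copy in place of its parent may account for families with a large gain of copies against the parent: the median loss of the parent over the gain of its copies was 1.03 in 6 such families under AngII (range 0.0923 to 1.57), and 0.862 in 7 under saline (0.375 to 1.81), or 0.81 without Rps3a1, where a plain shift of reads gives 1. In the other families with a called copy, the ratio ran from -1.85 (Glo1) to 4.00 (Rps15a) under AngII. Under saline it ran from -24.0 (Ftl1) to 1.94 (Rps2) in those others. A plain shift of reads was thus not seen in every family. A copy difference in the DNA of the animals or a difference in alignment may each play a part, and neither was tested. Copies of Rps3a1 held 46.7% of the family in KO saline but 0.840% in KO AngII, of the same genotype. Whether the values of both genotypes were made separately cannot be told apart from genotype. The 2725 genes without a symbol were those with 0 reads in all WT libraries. DNA of another strain around Vamp8 was argued against as the source of most genotype calls. Of those under saline, 99.2% lay outside 20 Mb of the gene. This does not cover calls near Vamp8. Within 10 Mb, 4 of 61 tested genes were called under AngII (6.56%, against 2.01% elsewhere) and 2 of 61 under saline (3.28%, against 3.02%). An effect of Vamp8 loss and strain DNA elsewhere in the genome stay open and were not tested.

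Mitochondrially encoded genes took 30.5% of counts in KO saline and 13.4% in WT saline. A bias by transcript length as the whole cause was argued against, since the median rise of these genes was 1.29 after removal of the length trend, from 1.64 before. Brown fat around the vessel, which is rich in mitochondria, may contribute, but the brown adipocyte score differed between KO and WT saline with an exact permutation p of 0.229. A WT saline library also reached a brown adipocyte score of 7.75, while the mitochondrial share was 17.7% or less in every WT saline library. The question stays open. RNA quality, handling of the KO saline group as a batch and an effect of Vamp8 loss also stay open, and no test separated them.

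Matrix genes were lower in KO than in WT aortae under both infusions. A length bias was argued against, since the median of the matrix genes was -0.774 after removal of the length trend under saline and -1.05 under AngII. Less arterial wall in KO samples may lower matrix and contractile genes alike: matrix minus contractile score differed by 0.0410 under saline (exact permutation p = 0.886) and by -0.817 under AngII (exact permutation p = 0.0857). Under AngII the matrix score differed by -0.91 (exact permutation p = 0.0286) and the contractile score by -0.0911 (exact permutation p = 0.914), so the contractile fall this explanation needs was not seen there, although the difference of both scores did not pass with 4 libraries against 4. A lower expression of matrix genes in KO smooth muscle cells or fibroblasts is a hypothesis that stays open beside a difference in tissue makeup and a difference in counting between genotypes.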

How the results depend on the processing

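The fit without the library labelled KO saline replicate 1 and KO AngII replicate 4 was chosen after the data were seen, and all other settings before. Counts are given for AngII in WT, AngII in KO, KO against WT under saline, KO against WT under AngII, the interaction and the average AngII effect, in this order, where edgeR gave 71, 8, 481, 324, 3 and 166. RLE scaling, the stricter filter, no filter, the robust fit and the fold threshold kept every count within 1.5 times. Single calls were still lost. Among 170 fold changes of named genes, which include values not called in the main fit, 1 lost its call under RLE, 9 without a filter and 2 in the robust fit. With 1 library left out, up to 40 lost it, without WT saline replicate 1. Only called values can lose a call, so the share of calls lost is larger than these counts over 170. DESeq2 gave 280, 734, 1362, 1230, 104 and 666, and limma voom with quality weights 254, 561, 3197, 580, 173 and 549. The adipocyte covariate gave 132, 17, 192 and 674 for the comparisons of pairs of groups. A fit of the compared groups alone gave 4 for AngII in KO, 203 under saline and 102 under AngII, and the fit without both libraries gave 128 for AngII in WT. The cause was not tested for any of these.

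The replicate number as a block gave 42 genes for AngII in WT, 14 for AngII in KO and 166 for KO against WT under AngII. The numbers do not pair the libraries: same-number correlations between groups were above 0.1 in 1 or 2 of 4 pairs, and not every library correlated best with its own number. The block changed no other count by over 1.5 times.

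Leaving out 1 library at a time gave 3 to 115 genes for AngII in WT, 6 to 32 for AngII in KO, 105 to 1744 for KO against WT under saline, 100 to 845 under AngII, 2 to 12 for the interaction and 42 to 252 for the average AngII effect. The average effect was 79, 68 and 100 without WT saline replicates 1, 3 and 4, 46 and 42 without WT AngII replicates 3 and 4, 63 and 68 without KO saline replicates 3 and 4, and 252, 80 and 109 without KO AngII replicates 1, 2 and 3. Lists called by camera ran over 17 to 25, 12 to 16, 16 to 22, 19 to 27 and 9 to 22, with 9 for the interaction without KO AngII replicate 4. An estimated correlation gave 0 lists in each of the 5 comparisons, and fry gave 1, 0, 0, 5 and 0. The correlation of AngII effects over genes called on the average effect, which the selection itself favours, ran over 0.566 to 0.805.

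The difference in AngII score ran over -0.45 to 0.55, and turned negative with the stricter filter (-0.0315), without WT saline replicate 2 (-0.45) and without WT AngII replicate 2 (-0.25). The interaction of Agtr1a turned from 1.34 to -0.22 by voom, and with 1 library left out it ran from -0.28, without KO AngII replicate 4, to 1.65. Its change with AngII in KO mice ran from -0.0303, without the same library, to 1.89. Genes near Vamp8 had an odds ratio of 1.09 within 10 Mb under saline, against 0.571 within 20 Mb, and 3.42 within 10 Mb under AngII (Fisher's exact p = 0.0350).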

Other observations

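Genes of the circadian clock and the SNARE genes other than Vamp8 were read from lists fixed before the data were examined, and the members named here were chosen after their values were seen. Clock genes differed between KO and WT aortae in both directions. Under saline 5 of 17 rose and 4 fell (8 and 4 adjusted over the list alone, median 0.71, camera adjusted p = 0.0305, adjusted p = 0.805 with an estimated correlation), and under AngII 8 rose and 2 fell (12 and 4 adjusted over the list alone, median 0.89, camera adjusted p = 7.52e-06, adjusted p = 0.212 with an estimated correlation, fry adjusted p = 0.00444). Arntl, a core activator of the clock, had log2 fold changes of -1.63 and -2.08 under saline and AngII (edgeR quasi-likelihood adjusted p = 0.0169 and 0.00377), and Npas2, which pairs with it, -2.12 and -2.41 (adjusted p = 0.0200 and 0.0112). Ciart, a repressor of the clock, had 2.91 and 2.85 (adjusted p = 0.00280 and 0.00336), and Dbp, a transcription factor under its control, 1.97 in both (adjusted p = 0.0414 and 0.0483). The hour at which each aorta was taken is not given in the sources used here.

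Vamp5 was the only other member of the SNARE list called in a comparison of KO with WT, with a log2 fold change of -1.05 under AngII (edgeR quasi-likelihood adjusted p = 0.00676). Whether the Vamp8 allele or DNA flanking it accounts for this fall was not tested. Lep, the adipocyte hormone leptin, rose by 3.41 log2 units in KO AngII against WT AngII (adjusted p = 0.000648).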
